A study of Homo sapiens with 3 samples.

How the data were processed

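The series holds chromatin immunoprecipitation sequencing (ChIP-seq) of histone H3 trimethylated at lysine 36 (H3K36me3) in LNCaP, an established androgen-responsive prostate cancer cell line. Per the labels, 3 libraries were made: untreated cells, cells given 100 nM dihydrotestosterone (DHT, the potent androgen made from testosterone) for 4 h in RPMI medium described as red-free, and an input library without antibody. Cells were kept in RPMI with 10% serum and libraries were started from 5 ng of DNA, per the labels' protocols. The untreated cells are labelled only as having no treatment, so a change of medium with the hormone cannot be separated from the hormone itself. The input library has no file among those used and was not analysed here. Each condition has 1 library, so no p-value was computed, and no interval covers the spread between libraries. Intervals cover counting error only, which treats peaks as independent although neighbouring peaks are not, except those for the end effect, which reflect the spread between chromosomes.

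For each ChIP library the authors deposited a list of peaks with chromosome, start, end, name and a score per peak. Peaks were called with MACS, per the peak names, and each library has its own list. The caller's version and settings, the control it used, the aligner and the read numbers are not given in the sources used here, so the sequencing depth behind each peak is unknown. The build is hg19, per the file names. The deposited score ran from 50 to 3100 in both lists. Its scale is not stated in the files, it is the authors' value for the peak, and it was used to rank or filter peaks within a list. The exception is the number of peaks at fixed scores, which sets both lists at the same score and so compares them only as far as their scales match. Calling many short peaks over a mark that forms broad domains can break 1 domain into several peaks, and a list of peaks shows where a threshold was passed, not the level of the mark.

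Peaks on chromosomes 1 to 22, X and Y were compared, and the few on mitochondrial DNA were set aside. Intervals are printed counting from 1. Overlap was counted with bedtools 2.31.1 and with a cumulative-length method in NumPy 2.4.6 under Python 3.11.15, which gave identical counts at a minimum overlap of 1 bp. As a reference for overlap, the DHT peaks were shifted in a circle along each chromosome by random distances, 100 times. Covered percentages were computed in windows of 1 Mb. A window was counted as marked at 10% covered and as changed at 10 percentage points. These rules were fixed before the data were examined, for gene bodies first and for windows if no annotation of the build was at hand. Only a table of GRCh38.p14 gene names was at hand, so hg19 peaks were not assigned to genes. Planned results on gene bodies, exons and introns were therefore not computed, and gene lists fixed beforehand could not be placed on hg19 coordinates and were not analysed here. From that table only the number of protein-coding genes per chromosome was used, 20033 in all, with none of its coordinates.

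By the rule fixed beforehand, the text names the 10 windows with the largest rise and the 10 with the largest fall. The rule also allowed the 10 widest peaks of each library, of which the widest and those without a counterpart are named, the latter chosen after their values were seen. Blocks were defined after the data were seen: peaks of both libraries at most 5 kb apart were joined, and blocks of at least 10 kb were compared by the length covered in each library. A chromosome end was taken as position 1 where a first peak lies within 1 Mb of it (not so on 7 chromosomes) and as the end of the last peak on the other side. Intervals for the end effect come from 1000 bootstrap resamples of the chromosomes. Shares of peaks carry 95% Wilson intervals. The interval for a ratio of covered lengths sums squared peak widths as a Poisson variance. The interval functions were tested on 5000 simulated peaks, where 5 of 5 known answers were recovered exactly. The check of joining at 1 kb used peaks too far apart to join, so joining itself was not tested. The matched-window percentile reached 100 when 200 simulated windows were raised by 1 SD.

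Alternatives tried were the higher-scoring 50% of each list, both lists trimmed by score to the same covered length, peaks joined at 1 kb and 5 kb, stricter overlap, other thresholds for windows and windows of 100 kb.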

Results

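H3K36me3 marks the bodies of transcribed genes, where it is laid down behind elongating RNA polymerase II. Its distribution was mapped in LNCaP cells without treatment and after 4 h of 100 nM DHT, with 1 library each, to compare the mark with and without added DHT. The untreated list held 117568 peaks and the DHT list 131801. Of these, 117564 and 131798 lay on nuclear chromosomes and entered the comparisons. They covered 64.3 Mb and 66.0 Mb of hg19. Median peak width was 374 bp in the untreated library and 354 bp after DHT. The narrowest peaks were 116 and 122 bp wide. The widest was 7628 bp in the untreated library, on chromosome 17 from 7123942 to 7131569, and 7885 bp after DHT, on chromosome 11 from 897415 to 905299.

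In both libraries the mark was concentrated on gene-rich chromosomes. Chromosome 19, which has the most protein-coding genes for its length, was the most covered, at 6.25% of its span in untreated cells and 7.15% after DHT. Chromosome 17 followed with 4.60% and 4.92%, and chromosome 22 with 3.79% and 4.23%. Among autosomes, gene-poor chromosome 13 was the least covered, at 0.811% and 0.836%. Chromosome X was at 0.727% and 0.711%, and Y at 0.171% and 0.151%. Span was counted from position 1 to the last peak, also on the 7 chromosomes whose first peak lies over 1 Mb in. Sequence before the first peak therefore lowers their covered percentage and their genes per Mb of span. The order of chromosomes by either measure may depend on this. Over the 24 chromosomes, covered length went with the number of protein-coding genes (Pearson r = 0.905 and Spearman rho = 0.889 untreated, 0.916 and 0.898 after DHT). The relation with span was lower (r = 0.636 and rho = 0.569 untreated, 0.576 and 0.526 after DHT). Without the chromosomes farthest from the median gene number, 1 and Y, r with gene number was 0.821 untreated and 0.846 after DHT. Chromosomes are not independent replicates, and 6 such relations were computed.

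**Figure D1:**
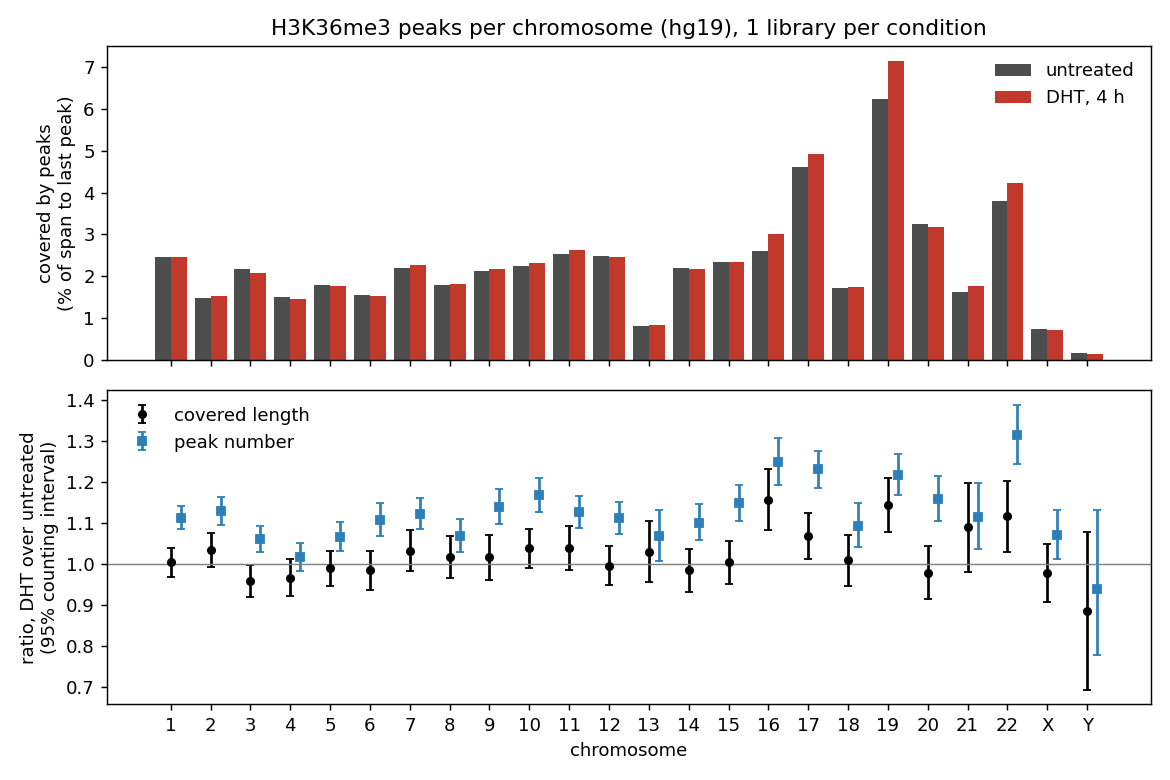
The upper bars give the percentage of each chromosome's span covered by H3K36me3 peaks in the untreated and the DHT library, and the lower points give the DHT over untreated ratios of covered length and of peak number with 95% counting intervals. Chromosome 19 was the most covered in both libraries, and the peak number ratio was highest on chromosome 22, at 1.31.

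The DHT library had more peaks of smaller width over nearly the same length. Its list was 1.12 times as long (95% counting interval 1.11 to 1.13), while covered length was 1.03 times that of untreated cells (1.01 to 1.04). Peak number was higher after DHT on 23 of 24 chromosomes, all but Y. Covered length was higher on 15 and lower on 9. Peaks of at least 2 kb were fewer after DHT, 2700 against 3036. This came from peaks of 2 to 4 kb, 2215 against 2623, while wider ones were more numerous after DHT, 485 against 413. With no replicate of either condition, how far 2 libraries of untreated cells would differ in these numbers is unknown.

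The counting interval of the covered length ratio excluded 1 on chromosomes 3, 16, 17, 19 and 22. Covered length on chromosome 16 was 1.16 times as high after DHT (1.08 to 1.23), on chromosome 19 it was 1.14 times as high (1.08 to 1.21), and on chromosome 22 it was 1.12 times as high (1.03 to 1.20). On chromosome 17 the ratio was 1.07 (1.01 to 1.12), and on chromosome 3 it was 0.959 (0.921 to 0.998). Intervals of the remaining 19 chromosomes included 1, among them chromosome 21 at 1.09 (0.982 to 1.20) and Y at 0.885 (0.693 to 1.08). Peak number ratios were highest on chromosome 22 (1.31), 16 (1.25), 17 (1.23) and 19 (1.22) and lowest on 4 (1.017) and Y (0.939). The peak number ratio went with protein-coding genes per Mb of span across the chromosomes (r = 0.633, rho = 0.761), and also without chromosomes 19 and 17 (r = 0.751, rho = 0.704). For the covered length ratio the corresponding values were r = 0.635 and rho = 0.421, and r = 0.550 and rho = 0.276 without chromosomes 19 and 17.

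About as much sequence was covered in both libraries as in either alone, far more than at shifted positions. Of the untreated peaks, 52.3% (52.0% to 52.5%) were overlapped by a DHT peak, and 48.5% (48.2% to 48.7%) of DHT peaks were overlapped by an untreated peak. Shared sequence came to 32.0 Mb, or 32.5% of all sequence covered in either library. Untreated-only sequence came to 32.4 Mb and DHT-only sequence to 34.0 Mb. Circular shifts of the DHT peaks left a mean of 1.32% shared (SD 0.0573 over 100 shifts, highest 1.496%). A fixed shift of 1 kb lowered the shared part to 10.6%, 10 kb to 5.37% and 1 Mb to 1.88%.

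Overlap was higher among peaks with higher scores, which were not separated from wider peaks. In the untreated library, 34.8% of the lowest-scoring 25% of peaks were overlapped and 77.0% of the highest-scoring 25%. After DHT the corresponding shares were 26.3% and 81.1%. Overlapped peaks had a median score of 97.4 against 70.3 for the others in the untreated list, and 113 against 72.5 in the DHT list. They were also wider, with medians of 479 against 317 bp and 410 against 328 bp. Of peaks at least 2 kb wide, 91.2% (90.1% to 92.1%) of the untreated and 76.7% (75.03% to 78.2%) of the DHT ones were overlapped. Among the 10 widest untreated peaks, those on chromosome 10 from 81062831 to 81070345 and on chromosome 19 from 54964584 to 54971666 had no DHT peak at all. Among the 10 widest DHT peaks, 4 had no untreated peak. They lay on chromosome 3 from 52510353 to 52518091, chromosome 11 from 70276841 to 70284476, chromosome 8 from 134469935 to 134477424 and chromosome 19 from 34291945 to 34299243. Their scores were 61.3, 114, 68.3 and 77.7 in that order, against a list median of 85.7. The untreated peaks on chromosomes 10 and 19 scored 79.7 and 97.0, against 81.2. The other 8 untreated peaks were covered over 21.5% to 99.6% of their width, and the other 6 DHT peaks over 28.9% to 94.6%.

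At the scale of 1 Mb the maps were close, with r = 0.976 and rho = 0.987 across 3107 windows. Of these, 2786 held a peak of either library, and those at 0 in both also entered the correlations and medians. In windows of 100 kb, r was 0.942 and rho 0.882. At least 10% of the window was covered in 42 windows of untreated cells and in 73 after DHT, 34 of them in both. In untreated cells the most covered windows were chromosome 19 from 58000001 to 59000000, at 16.6%, and chromosome 9 from 131000001 to 132000000, at 15.5%. After DHT they were chromosome 11 from 1 to 1000000, at 16.7%, and the same chromosome 9 window, at 16.6%. No window differed by 10 points or more in either direction. That rule was first set for gene bodies and could hardly be met here, with median coverage of 1.12% untreated and 1.04% after DHT. A fall of that size was possible only in the 42 untreated windows at 10%. Coverage was higher after DHT by at least 2 points in 59 windows and lower by as much in 3. Of all windows, 1300 were higher after DHT and 1486 lower. This majority turned to windows higher after DHT when each list was first joined at 1 kb or 5 kb. At 1.5-fold, with at least 10 kb covered, 46 were higher and 50 lower. In windows of 100 kb, 1.5-fold with at least 10 kb covered gave 316 higher and 118 lower. There 10 kb is a larger part of the window, so only 2195 of 30940 windows qualified, against 1666 of 3107 at 1 Mb.

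The windows with the largest rise all lay near chromosome ends. The first megabase of chromosome 11 went from 10.7% to 16.7%, a change of 6.005 points. On chromosome 19, the window from 3000001 to 4000000 went from 5.96% to 11.2%, that from 1 to 1000000 from 6.11% to 10.5% and that from 1000001 to 2000000 from 9.70% to 13.9%. On chromosome 16, the window from 2000001 to 3000000 went from 9.89% to 14.95% and that from 1 to 1000000 from 9.92% to 14.02%. The window from 139000001 to 140000000 on chromosome 9 went from 9.41% to 14.5%. The window from 1000001 to 2000000 went from 10.4% to 15.3% on chromosome 1 and from 5.86% to 9.77% on chromosome 7. On chromosome 8, the window from 145000001 to 146000000 went from 9.69% to 14.6%. All 10 were within 5 Mb of a chromosome end, where 7.05% of windows lie. All 10 were also higher after DHT in the higher-scoring 50% of the lists. Those peaks are part of the lists from which the windows were chosen, so this is no separate support.

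Falls were smaller and mostly lay inside chromosomes. The largest was at the end of the long arm of chromosome 19, from 58000001 to 59000000, where coverage went from 16.6% to 13.0%, a change of -3.63 points. This was the only 1 of the 10 within 5 Mb of an end. Coverage went from 4.79% to 2.61% on chromosome 20 from 9000001 to 10000000, from 6.70% to 4.66% on chromosome 4 from 77000001 to 78000000 and from 4.15% to 2.26% on chromosome 2 from 181000001 to 182000000. The other 6 differed by -1.87 to -1.54 points. They lay on chromosome 20 from 34000001 to 35000000, chromosome 3 from 15000001 to 16000000, chromosome 21 from 17000001 to 18000000, chromosome 9 from 35000001 to 36000000, chromosome 15 from 43000001 to 44000000 and chromosome 14 from 24000001 to 25000000. All 10 were lower after DHT in the higher-scoring 50% of the lists as well, which for the same reason is no separate support.

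**Figure D2:**
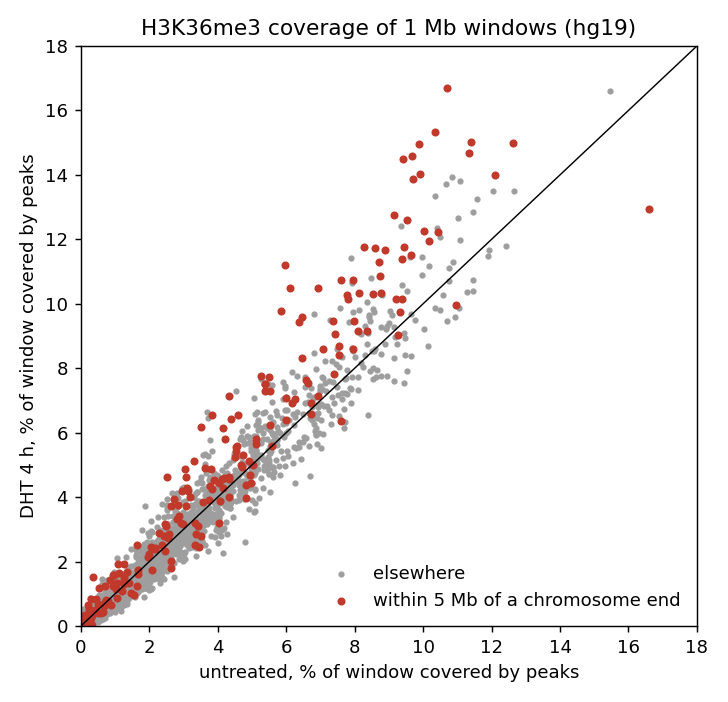
Each point is a 1 Mb window of hg19, with the percentage covered by H3K36me3 peaks in the untreated library on the x axis and in the DHT library on the y axis, and the line marks equal coverage. Windows within 5 Mb of a chromosome end mostly lie above the line, and the exception at the right, 16.6% against 13.0%, is on chromosome 19.

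Sorted by distance to the nearest chromosome end, mean coverage was 4.84% in untreated cells and 6.03% after DHT within 2 Mb, where 79 windows were higher after DHT and 16 lower. It was 3.55% and 4.21% at 2 to 5 Mb, 2.73% and 2.93% at 5 to 10 Mb, and 2.45% and 2.55% at 10 to 20 Mb. Beyond 20 Mb it was 1.75% and 1.70%, with 845 windows higher and 1157 lower. There the direction depended on joining. With each list joined at 1 kb, coverage beyond 20 Mb was 2.03% and 2.02%, with 913 windows higher and 1089 lower. Joined at 5 kb, it was 5.12% and 5.52%, with 1099 higher and 903 lower. Taken over 5 Mb, the DHT over untreated ratio of covered length was 1.22 near the ends and 0.994 elsewhere, so the ratio between them was 1.22 (95% bootstrap interval over chromosomes 1.18 to 1.27). This division by distance was chosen after the windows had been ranked. Peaks of at least 2 kb differed most: their covered length was 1.47 times as high after DHT near the ends, 3.09 against 2.10 Mb, and 0.767 times as high elsewhere, 5.29 against 6.90 Mb. Narrower peaks gave ratios of 1.14 and 1.03.

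**Figure D3:**
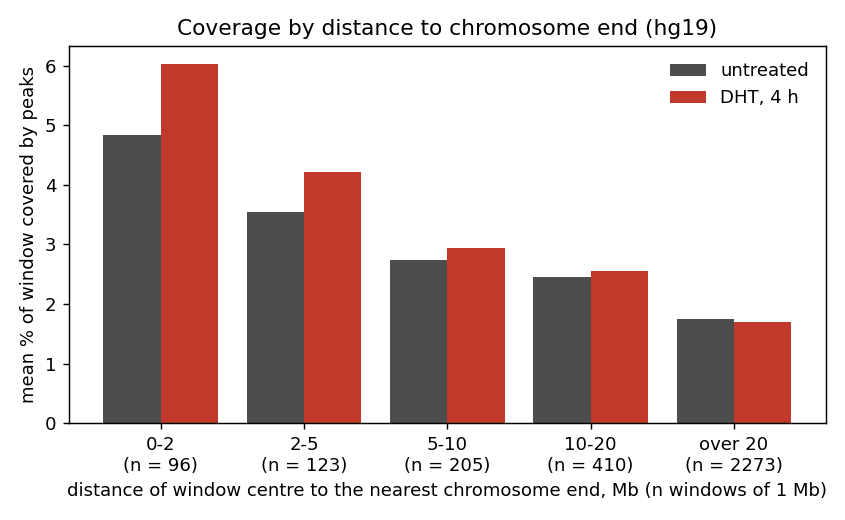
Bars give the mean percentage of 1 Mb windows covered by H3K36me3 peaks in the untreated and the DHT library, grouped by the distance of the window's centre to the nearest chromosome end, with the number of windows under each group. Coverage was 4.84% against 6.03% within 2 Mb of an end and 1.75% against 1.70% beyond 20 Mb.

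Joining peaks of both libraries at most 5 kb apart gave 67114 blocks, of which 9168 were at least 10 kb long. The longest, 142994 bp, lay on chromosome 3 from 47605805 to 47748798 and held 21940 bp of untreated and 22013 bp of DHT peaks. Nearly all blocks of at least 10 kb, 99.6%, held peaks of both libraries. Those with at least 5 kb covered in either library numbered 2676. Among these, 42 were at least 4-fold more covered after DHT and 13 at least 4-fold less. The blocks named next were chosen after their values were seen.

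Several blocks with few or no peaks in untreated cells were widely covered by peaks after DHT. On chromosome 8, from 134466630 to 134488807, covered length was 1077 bp in untreated cells and 12460 bp after DHT. On chromosome 9, from 139269384 to 139289949, it was 3206 and 14776 bp. On chromosome 4, from 6606179 to 6631762, it was 1251 and 11729 bp. A pair of neighbouring blocks on chromosome 16, from 1816897 to 1831517 and from 1854105 to 1873198, had 838 against 9985 bp and 2784 against 11695 bp. With no untreated peak, 8382 bp were covered after DHT on chromosome 6 from 35045121 to 35056991, 8375 bp on chromosome 19 from 1408750 to 1420234 and 7562 bp on chromosome 19 from 15289027 to 15301116. Of the 42 blocks, 10 lay on chromosome 19, 7 on chromosome 16 and 5 on chromosome 17, and 18 lay within 5 Mb of an end. Shares of all 2676 compared blocks in these places are not given, so no concentration can be read from these counts or those below. In the higher-scoring 50% of the lists 47 blocks met the rule, of which only 10 were among these 42. The chromosome 19 block from 1408750 to 1420234 rested on DHT peaks scoring 70.5, 50.3 and 74.1, below that list's median of 85.7. In the chromosome 8 block DHT scores ran from 58.0 to 236, and the widest DHT peak scored 68.3.

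Other blocks were covered in untreated cells and mostly or wholly lacked peaks after DHT. On chromosome 19, from 36212160 to 36235232, covered length was 16944 bp in untreated cells and 2921 bp after DHT. On chromosome 1, from 44034960 to 44050283, it was 11408 bp against none, with peaks in both libraries on either side. On chromosome 22, from 38454896 to 38469408, it was 12166 and 1710 bp. On chromosome 9, from 139983559 to 139998670, it was 10472 and 2395 bp, and on chromosome 7, from 4820273 to 4834601, it was 6788 bp against none. Of the 13 blocks, 4 lay within 5 Mb of an end, and 4 were among the 9 that met the rule in the higher-scoring 50% of the lists. The peaks that carried the blocks had median scores close to that of their list, 84.8 against 85.7 after DHT and 82.3 against 81.2 in untreated cells. Among peaks of at least 2 kb they scored lower than others of that width, with medians of 106 against 160 after DHT and 86.8 against 138 in untreated cells.

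**Figure D4:**
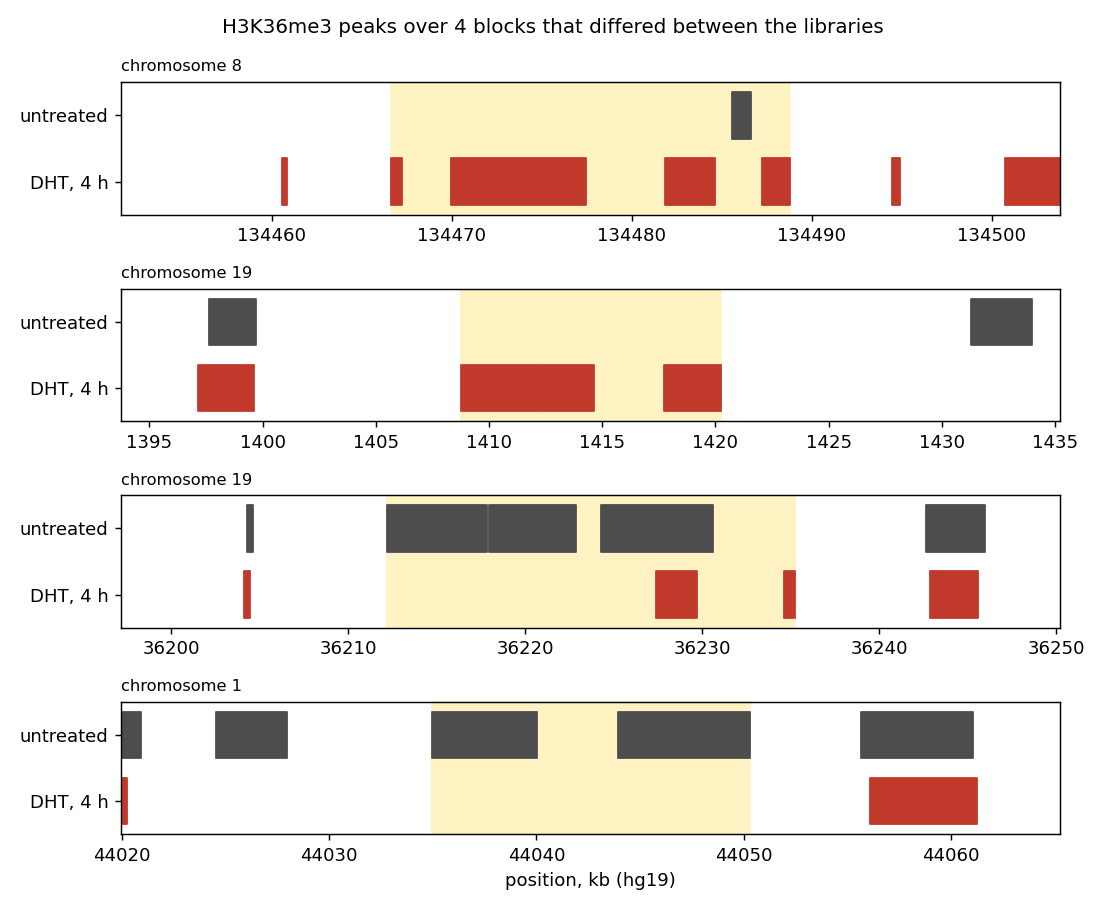
Each panel shows the H3K36me3 peaks of the untreated and the DHT library as bars along hg19 (position in kb) over a block that differed between them, shaded, with 15 kb on either side. On chromosomes 8 and 19 (upper panels) covered length was 1077 against 12460 bp and 0 against 8375 bp, and on chromosomes 19 and 1 (lower panels) it was 16944 against 2921 bp and 11408 against 0 bp.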

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

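Peaks on mitochondrial DNA, which has no histones, were outside the comparisons. The untreated list held 4 such peaks, covering 2601 bp with scores of 56.6 to 155, and was flagged for passing a fixed count floor of 3. The DHT list held 3, covering 1764 bp, so this does not set the lists apart.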

How the results depend on the processing

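Score cut-offs above 50, the end-distance and block results, and the 1.5-fold rule were chosen after the data were seen. The ratio of peak number, 1.12, stayed above 1 under every list setting run, at 1.12 in the higher-scoring 50% (by construction), 1.09 at the same covered length, 1.11 joined at 1 kb and 1.047 joined at 5 kb. It was 1.21, 1.26, 1.42 and 1.58 at scores of at least 75, 100, 200 and 300, if the scores of both lists share a scale. The covered length ratio, 1.03, was 1.01 in the higher-scoring 50%, 1.048 joined at 1 kb and 1.14 joined at 5 kb, and is 1 by construction at the same covered length. Untreated and DHT peaks overlapped, 52.3% and 48.5%, became 51.03% and 47.0% in the higher-scoring 50%, 51.5% and 49.2% at the same covered length, 55.7% and 50.7% joined at 1 kb, and 62.9% and 58.4% joined at 5 kb. Requiring 50% of the peak to be covered gave 44.0% and 45.2%, and doing so in both directions gave 41.1% and 36.6%. Windows at 10% covered, 42 and 73, became 1 and 5 in the higher-scoring 50%, which has less sequence to cover them, 76 and 120 joined at 1 kb, and 708 and 833 joined at 5 kb. Any covered base gave 2716 and 2734 windows, and 25% or 50% gave 0 and 0. Windows of 100 kb gave 1728 and 1819. Windows higher and lower after DHT by 10 points, 0 and 0, became 17 and 1 joined at 5 kb, 4 and 0 at 5 points, and 36 and 2 in windows of 100 kb. By a 1.5-fold rule with at least 10 kb covered they were 46 and 50. The excess of rises in 1 Mb windows thus did not appear by this rule, which also admits thinly covered windows. Windows with peaks were also sorted into 10 groups by mean coverage over both libraries. The DHT over untreated ratio of covered length was 1.09 in the most covered group and 1.03 in the next. It was below 1 in groups 2 to 8, counted from the least covered, and 1.24 in the least covered. In windows of 100 kb, 1.5-fold with at least 10 kb covered gave 316 and 118. That length is a larger part of a 100 kb window, so window size and the coverage required changed together. The ratio between chromosome ends and elsewhere, 1.22, was 1.18 within 10 Mb, 1.24 within 2 Mb and 1.24 without chromosome 19, and ranged from 1.20 to 1.26 over the list settings. Blocks higher and lower at least 2-fold numbered 216 and 73, against 42 and 13 at 4-fold. The causes of these movements were not tested beyond what each setting does by construction. Shifts between the first and last peak left 1.37% shared. Gene-body, exon and gene-list alternatives were not run, because no hg19 annotation was used here. Read depth is unknown, and with 1 library per condition no setting measures the spread between libraries of the same condition.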

Other observations

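The tests on base composition, on depth, on both block explanations and on joined isolated peaks were chosen after the result was seen, as were the blocks themselves. The covered part of a block often lay to 1 side of its middle, and mostly to the same side in both libraries. Of 5539 blocks of at least 10 kb with 2 kb or more covered in each library, 1868 had the centre of their untreated peaks displaced by at least 0.1 of the block's length. The DHT peaks were displaced to the same side in 1413 of these, or 75.6%. The rank correlation of the displacement between libraries was 0.426, against at most 0.0280 when the DHT peaks of each block were placed at random, 100 times. Random placement also removes the overlap of the peaks themselves, which alone gives a positive correlation, so this says nothing further about orientation.

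The rise of coverage near chromosome ends was set against 3 technical explanations. Calls near the lowest score alone are argued against, since the ratio between ends and elsewhere was 1.26 (1.19 to 1.34) in the higher-scoring 50% of each list. That cut is itself a threshold, at the median scores of 81.2 untreated and 85.7 after DHT. Small differences in score around any threshold therefore stay open. A rise of all heavily covered windows is argued against too. The mean change at the 212 end windows with peaks was 0.922 points. That was above all 10000 sets of interior windows matched on coverage (percentile 100, highest set 0.280). Those sets drew windows singly, while end windows are neighbours and were grouped after the largest rises were seen, so the sets understate the spread. Base composition stays open, because gene-rich chromosome ends also tend to be GC-rich and no hg19 sequence was used; the peak number ratio rose with gene density over chromosomes (rho = 0.761), which base composition and a hormone effect on gene-rich regions would both give. A difference in fragmentation or amplification between 2 single libraries and an effect of DHT or of the medium cannot be told apart here.

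The larger number of narrower peaks after DHT was set against splitting of the same blocks and against depth. Splitting alone is argued against, since peaks over 5 kb from any peak of the other library were 1.32 times as numerous in the DHT list (1.30 to 1.35), and 1.27 times (1.24 to 1.30) when each list was first joined at 5 kb. Splitting may still account for part, since other peaks were only 1.09 times as numerous and the ratio of all peaks was 1.047 after joining at 5 kb. A deeper or more strongly enriched DHT library stays open. The ratio rose from 1.12 at a score of at least 50 to 1.26 at 100 and 1.58 at 300. At 1000 or more there were 60 DHT and 20 untreated peaks. This is the direction set for that explanation. It does not decide the question, since the lists may differ in score scale. Read numbers are not given in the sources used here, so depth and hormone cannot be told apart.

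Blocks covered at least 4-fold more in 1 library, most of which had peaks in both, could reflect calls near the threshold. Their carrying peaks had median scores at the 49.3 and 50.98 percentiles of the DHT and untreated lists, which decides nothing. A second version of the test, tried after the first was seen, compared them with peaks of at least 2 kb only and gave 30.3 and 25.03, on the side of weak calls. Lower depth in untreated cells stays open too: 76.4% of the 55 blocks (63.7% to 85.6%) were higher after DHT, under the 95% set for it, but calls near the threshold would go both ways under a depth difference. Blocks such as that on chromosome 8 from 134466630 to 134488807 stay open as possible responses to androgen, which was not tested.

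The highest score in both lists, 3100, was at nearly the same place on chromosome 1, from 121483977 to 121485513 in untreated cells and from 121484043 to 121485519 after DHT, at the edge of a stretch of 21.1 Mb without peaks. Of the 10 highest-scoring peaks, 3 in the untreated list and 4 in the DHT list lay within 1 Mb of the longest peak-free stretch of their chromosome, where 1.04% and 1.019% of all peaks lay. On chromosome 19, the block from 36212160 to 36235232 was less covered after DHT but kept a DHT peak with a score of 615.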
